A study of Mus musculus with 3 samples.

How the data were processed

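RNA sequencing libraries of mixed glomerular mesangial and endothelial cells were analysed from 1 table of 39304 rows and 3 columns, 1 per aliquot of a cDNA pool of 30 cells. Per the submitters' processing notes, GRCm38, TopHat2 2.0.12 and HTSeq 0.6.1 were used; their settings, the annotation release and the gene length definition are not given in the sources used here. The values deposited by the authors are FPKM, per kilobase of gene length and per 1000000 reads of each library, with no further normalisation between aliquots. Of the rows, 39179 carry Ensembl gene identifiers and 125 carry another name, with no coordinates in the sources used here. Symbols came from the reference's name table, which matched 37607 identifiers and left 1572 without a symbol. Coordinates and transcript lengths came from GENCODE M21 on GRCm38, which may not be the authors' release. All columns were mapped to samples by their titles, and the replicate number is the aliquot number.

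Low FPKM values step in whole multiples of what 1 read is worth, so read numbers were recovered. Library totals were taken from the most frequent value of 1 read over genes under 0.5 FPKM, with the mean transcript length assumed for each. For each gene the smallest whole length that made all 3 read numbers whole within 0.0001 reads was sought. Where a whole multiple of that length lay within 1 base of the mean transcript length, the multiple was used instead (374 genes). A solution was found for 11142 of 11142 genes above 0. With totals moved slightly, 0% of 749 control genes had a solution within their longest transcript, against 93.6% with the recovered totals. The recovered reads of all genes add up to 96.7% of each total. A common factor of the 3 read numbers of a gene cannot always be resolved, so reads of some genes are too low by a whole factor, which lowers the chi-square statistic. A multiple used wrongly would raise it. Of 9215 genes with transcripts of different lengths, 44.0% had an implied length within 1 base of the mean transcript length and 3.14% within 1 base of the longest. The use of multiples builds in part of the match to the mean. Shorter implied lengths raise FPKM, so levels of different genes depend on that choice. On simulated data of 1476 genes the recovery returned 100% of reads up to a common factor. The true lengths there were set to the mean transcript length that the search for totals assumes. The simulation therefore does not test totals where gene lengths differ from that mean. No count model was run, since the deposited unit is FPKM.

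Detection was defined as at least 1 FPKM in every aliquot. Agreement was computed on log2(FPKM + 1) as Pearson's r and Spearman's rho across genes, and as the coefficient of variation per level class. Spread was compared with sampling noise by a chi-square test of recovered reads against the library totals for genes with at least 30 reads, with Benjamini-Hochberg adjustment at 0.05. Before the data were examined, 15 cell type lists (1 of them the 7 selection genes), 18 gene groups and 25 gene pairs were fixed. The cell types are mesangial, endothelial, podocyte, parietal epithelium, proximal tubule, distal nephron and collecting duct, smooth muscle and renin cells, fibroblast, macrophage and dendritic cell, lymphocyte, neutrophil, erythroid, arterial endothelium, and venous, lymphatic and peritubular endothelium. The selection genes were left out of the mesangial, endothelial and podocyte lists because they chose the cells. All members were measured.

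List means of log2(mean FPKM + 1) were compared by a two-sided permutation of list membership across genes with 100000 resamples, with Benjamini-Hochberg adjustment over 14 comparisons and a threshold of 0.05. Differences are on the log2(FPKM + 1) scale, which understates those of low genes. On 200 pairs of simulated lists of 14 and 15 genes drawn from 11142 genes, 6% gave p under 0.05 with no shift, 58% with a shift of 2 and 99% with a shift of 4 in log2. These simulated lists held only genes above 0 in some aliquot and used 10000 resamples. The rates need not hold for lists of other sizes or with most members at 0. Each list's median was placed among 10000 random lists, not matched on level because level is the measure. Pairs were given as mean and SD of log2 ratios with no test.

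Genes were named by a rule fixed beforehand: the 7 selection genes, up to 4 highest detected and up to 4 lowest undetected members of each list, the 20 genes with the highest mean FPKM, the 10 with the largest SD of log2(FPKM + 1) among those of at least 10 FPKM, and both genes of each pair. Genes outside it are said to be chosen after their values were seen. A few genes that the rule names, and 1 of the gene pairs, are not reported or drawn here, though counts and tests include them. Alternatives fixed beforehand were other detection limits (0.5 and 5 FPKM, or 1 FPKM as the mean), a pseudocount of 0.1 FPKM, medians, filters on low values, leaving out the highest member, rescaling to a sum of 1000000 or by median ratios, putting back the selection genes, other reference lists, other random backgrounds and leaving out each aliquot. Gene length changed to the longest transcript and the podocyte list without Podxl were added after seeing the data. The first was run by multiplying FPKM by the implied over the longest annotated length, and also by the mean length, rounded to a whole base, over the longest. The mean was added after the rank of Gata3 had been seen, because an implied length can miss a whole factor. It is an approximation where the authors' length differs from the mean: Notch3 has an implied length of 8044 bases and a mean of 3126. The 125 rows without an Ensembl identifier entered the counts of genes, the correlations, the noise test and the random lists, and no list or pair. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.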

Results

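The libraries came from glomeruli, the filtering units of the kidney, of 1 wild-type male C57BL/6 mouse aged 8 weeks. Single cells were lysed and their RNA copied to cDNA in the wells of a Fluidigm C1 microfluidic system, and each well was assigned a cell type by qPCR of marker genes. The cDNA of 15 mesangial cells, the contractile supporting cells between glomerular capillaries, and of 15 endothelial cells, which line those capillaries, was mixed and divided into 3 aliquots that were made into libraries and sequenced. All 3 libraries therefore belong to 1 group, and their spread measures library construction and sequencing only. No value below has a check across mice, and every SD is over the 3 aliquots (n = 3). The library totals behind the deposited FPKM values (fragments per kilobase of gene and per 1000000 reads) were 9141422, 10427635 and 10976563 reads for aliquots 1, 2 and 3.

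The most abundant transcripts of the pool were nuclear, cytoskeletal and mitochondrial, with a pair of mesangial genes among the first 20. In the deposited FPKM the nuclear RNA Malat1 had the highest level, 19980 ± 188 FPKM, followed by the actin gene Actb with 18162 ± 164 FPKM. The next 4 ranks were mitochondrial, led by mt-Co3 with 12276 ± 288 FPKM and mt-Atp6 with 10485 ± 469 FPKM. The septin Sept2 (4927 ± 31.2 FPKM), the G protein subunit Gnb1 (4028 ± 30.8 FPKM), Ywhaz (3177 ± 35.7 FPKM) and the actin-binding peptide gene Tmsb4x (3134 ± 69.1 FPKM) followed. Gata3, a transcription factor used to recognise mesangial wells, stood at rank 12, and Serpine2, a protease inhibitor on the mesangial list, at rank 19 with 1895 ± 22.9 FPKM. This order depends on gene length, in alternatives chosen after seeing the data. With lengths scaled to the longest transcript from the mean or from the implied length, mt-Co3 and mt-Atp6 took ranks 1 and 2, Malat1 rank 5, Actb rank 3 or 6 and Gata3 rank 32. By each of them 16 of the 20 genes stayed among the first 20, and Serpine2 had rank 27 or 17. The 20 genes with the most reads took 14.6% ± 0.160 of all reads, and Malat1 alone 3.73% ± 0.0350.

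A total of 8537 genes reached 1 FPKM in every aliquot, of which 7761 were protein-coding. The mean was at least 10 FPKM for 5666 genes, at least 100 FPKM for 1169 genes and at least 1000 FPKM for 51 genes. The table listed 28162 of its 39304 rows at 0 in all aliquots. Some zeros concern genes that most cells use: mt-Nd4l was listed at 0 in each aliquot while its neighbour mt-Nd4 had 1233 ± 59.1 FPKM. The mitochondrial ribosome gene Mrps22, the cytochrome oxidase assembly gene Cox20 and the splicing factor Srsf4, named after their values were seen, were also listed at 0 in each. A zero is therefore reported only as listed, not as absence of the transcript. A count of 3 reads corresponded to 0.328, 0.288 and 0.273 reads per 1000000 in aliquots 1, 2 and 3, and to 0.0982 over the 3 together, for counting error only.

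The aliquots gave nearly the same profile. Across the 11142 genes above 0 in at least 1 aliquot, Pearson's r of log2(FPKM + 1) was 0.9969 between aliquots 1 and 2, 0.9969 between 1 and 3 and 0.9973 between 2 and 3. Spearman's rho was 0.9947, 0.9945 and 0.9951. These are correlations across genes, which are not independent replicates, so no p-value is given. The median coefficient of variation fell with level, from 35.1% for genes of 0.1 to 1 FPKM through 9.91% for 1 to 10 FPKM and 4.05% for 10 to 100 FPKM to 2.16% for 100 to 1000 FPKM and 1.67% above that. Among abundant genes the mitochondrial transcripts moved together: all 12 with reads were higher in aliquot 1 than in the mean of the others, with a median log2 ratio to the other aliquots of 0.10. Their share of reads was 4.37%, 4.17% and 4.18% in aliquots 1, 2 and 3. A chi-square test on the recovered reads with Benjamini-Hochberg adjustment found 99 of 9120 genes with at least 30 reads beyond sampling noise, 8 of them mitochondrial, and 66 of the 99 were higher in aliquot 1. The calls rose with depth, from 3 of 1013 genes with 30 to 100 reads to 53 of 506 with at least 10000. The mean chi-square statistic was 1.15 times its sampling value in the first of these classes, 1.21 and 1.43 times in the classes between and 4.62 times in the last. The median was 1.14, 1.20, 1.39 and 2.21 times its sampling value in the same order, so the mean of the last class exceeds its typical gene. The test counts reads of amplified cDNA as independent molecules, so it covers counting error only. The 10 genes with the largest SD of log2(FPKM + 1) among those of at least 10 FPKM held 0 protein-coding genes. They were short RNAs such as Gm22549 (SD 0.82) and Snord83b (SD 0.75) and the pseudogene Rps25-ps1, each with 31 to 142 reads in total.

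The design mixed cells chosen by 7 marker genes, so these were examined first. The mesangial markers were the highest: Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034, minus strand, GRCm38) had 2992 ± 208 FPKM and Igfbp5 (ENSMUSG00000026185, chromosome 1, 72857932 to 72874884, minus strand), a binding protein of insulin-like growth factors, 950 ± 11.8 FPKM. The endothelial markers were lower. Pecam1 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628, minus strand), which encodes the adhesion molecule CD31, had 105 ± 1.28 FPKM, and Tek (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976, plus strand), the angiopoietin receptor Tie2, had 42.2 ± 1.07 FPKM. The podocyte markers, which named the glomerular epithelial cell type left out of the mixture, were also measured. Wt1 (ENSMUSG00000016458, chromosome 2, 105126529 to 105173616, plus strand), a transcription factor, had 101 ± 3.18 FPKM, and Synpo (ENSMUSG00000043079, chromosome 18, 60593973 to 60660142, minus strand), an actin-associated protein, had 36.7 ± 1.04 FPKM. Each of these genes is quoted with the whole gene's coordinates, and FPKM counts reads over its exons. The Gata3 level rests on a short gene length: the values imply 915 bases, while the longest annotated transcript has 3215.

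Further mesangial markers, not used to choose the cells, were then set against further podocyte markers. All 14 mesangial markers were detected, that is, at or above 1 FPKM in every aliquot, with a median of 288 FPKM. The highest were Serpine2, the G protein regulator Rgs5 (1571 ± 36.1 FPKM), the integrin Itga8 (667 ± 6.19 FPKM) and the Wnt antagonist Sfrp2 (632 ± 12.1 FPKM). Of the 15 podocyte markers 8 were detected, with a median of 1.80 FPKM. Podxl, a sialomucin that endothelial cells make too, had 75.9 ± 2.15 FPKM, nephrin (Nphs1) 37.6 ± 2.37 FPKM, Thsd7a 29.6 ± 1.17 FPKM and the cell cycle inhibitor Cdkn1c 14.02 ± 0.597 FPKM. The lowest were Clic3 (0, 0 and 0.126 FPKM in aliquots 1, 2 and 3) and the transcription factor Lmx1b (0.237 ± 0.111 FPKM), with Kirrel (0.631 ± 0.205 FPKM) and Ptpro (0.887 ± 0.135 FPKM) above them. On the log2(FPKM + 1) scale the mesangial list had a mean of 7.85 and the podocyte list 2.20, a difference of 5.65 (permutation test of list membership across genes, two-sided, p = 2e-05, Benjamini-Hochberg adjusted p = 4e-05 over 14 comparisons). The difference was 5.57, 5.69 and 5.70 in aliquots 1, 2 and 3. This test and those that follow permute genes, which are not independent replicates, so each p describes these lists in this pool and not other mice.

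Endothelial markers were detected for 14 of 16 members, with a median of 106 FPKM. The sialomucin Emcn led with 1282 ± 22.1 FPKM, followed by the tissue plasminogen activator gene Plat (384 ± 0.654 FPKM), Ehd3, a glomerular endothelial gene (313 ± 4.42 FPKM), and the TGF-beta co-receptor Eng (286 ± 4.01 FPKM). The tight junction gene Cldn5 was listed at 0 in each aliquot, and Nos3, the endothelial nitric oxide synthase, had 0.0279, 0 and 0 FPKM. The endothelial mean of 5.79 lay 3.59 above the podocyte mean of 2.20 (permutation test across genes, two-sided, p = 0.00084, Benjamini-Hochberg adjusted p = 0.0012), with differences of 3.52, 3.62 and 3.64 in the 3 aliquots.

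Equal numbers of mesangial and endothelial cells were pooled, and their marker lists were compared directly. The endothelial mean of 5.79 was below the mesangial mean of 7.85, a difference of -2.06 (permutation test across genes, two-sided, p = 0.042, Benjamini-Hochberg adjusted p = 0.042), with -2.05, -2.07 and -2.07 in the 3 aliquots. The call ended when medians were compared (-1.52, adjusted p = 0.21) and when members under 0.1 FPKM, Cldn5 and Nos3, were left out (-1.23, adjusted p = 0.16), and the adjusted permutation p ranged from 0.012 to 0.21 over all alternatives. Different genes make up the lists, so the difference does not measure the share of either cell type.

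**Figure D1:**
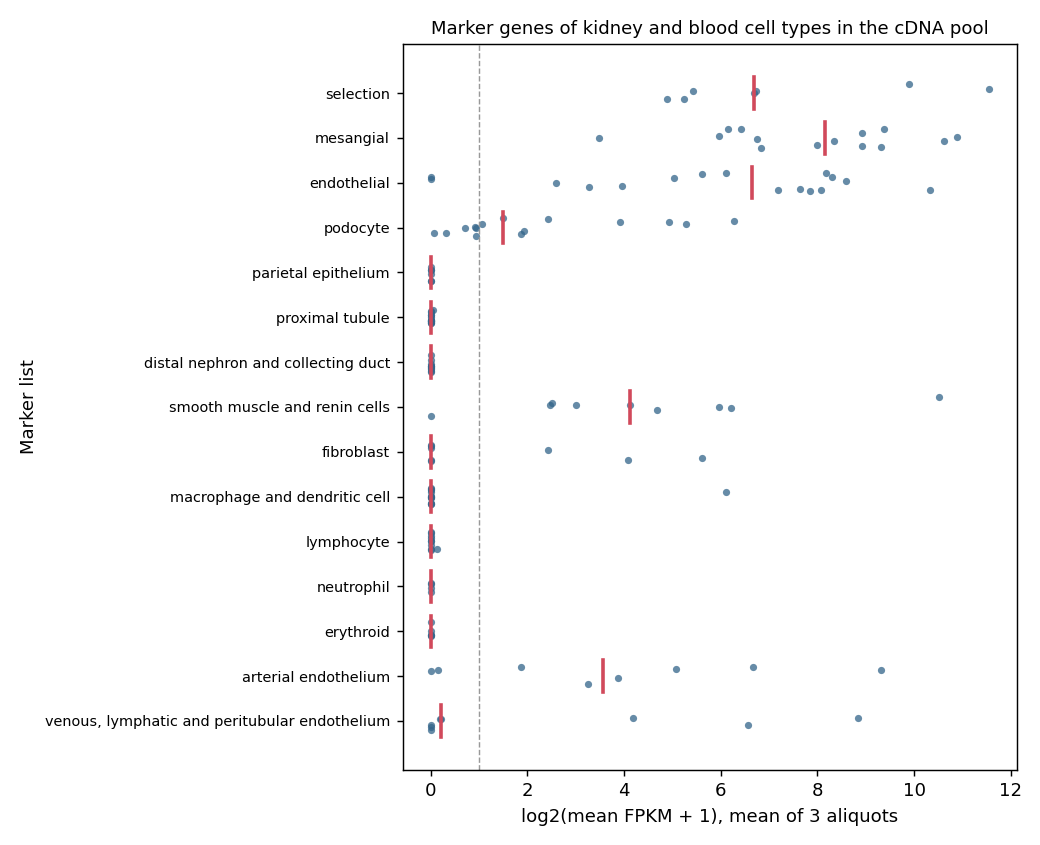
Levels of marker genes by list. Each blue point is 1 gene at log2(mean FPKM + 1) over the 3 aliquots (x axis), in rows by marker list with vertical jitter for legibility; red bars are list medians and the dashed line marks 1 FPKM. The mesangial median is 288 FPKM, the endothelial 106 FPKM and the podocyte 1.80 FPKM, while tubule and most blood cell lists lie at 0.

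Lists of 11 other cell types were set against the pooled mesangial and endothelial markers (30 genes, mean 6.75) to see at what levels markers of other cells were listed. Epithelial markers of the nephron were not detected: 0 of 6 for the parietal epithelium of the glomerular capsule, 0 of 14 for the proximal tubule and 0 of 10 for the distal nephron and collecting duct. Single reads in 1 aliquot gave Ncam1 and Ass1 means of 0.0107 and 0.0340 FPKM, and the tubule genes Lrp2, Slc34a1, Umod and Aqp2 were listed at 0 in each aliquot. Blood cell markers were not detected either, with 0 of 10 lymphocyte, 0 of 4 neutrophil and 0 of 5 erythroid markers detected. Lck reached 0.0918 ± 0.0959 FPKM, and the haemoglobin genes Hba-a1 and Hbb-bs and the neutrophil genes S100a8 and S100a9 were listed at 0 in each. Of 12 macrophage and dendritic cell markers 1 was detected, the Fc receptor chain Fcer1g with 68.0 ± 1.74 FPKM, while Ptprc, Cd68, Adgre1 and Csf1r were listed at 0. Of the 61 members of these 7 lists 57 were listed at 0, so their tests compare listed values and do not show that a cell type was absent. The differences from the pooled markers ranged from -6.75 for the distal nephron, whose members were all at 0 as were those of neutrophils and erythroid cells, to -6.25 for macrophages (permutation tests across genes, two-sided). The Benjamini-Hochberg adjusted p was 3.5e-05 for the nephron epithelia and lymphocytes, 4e-05 for macrophages and erythroid cells and 0.00017 for neutrophils, whose test was exact. The unadjusted p of 1e-05 behind the first of these is the smallest the resampling can give. With members under 0.1 FPKM left out, the macrophage list kept Fcer1g alone (-1.13, adjusted permutation p = 0.62; range over all alternatives 2.8e-05 to 0.62) and the other 6 lists gave no value.

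Mural and stromal markers were detected in part. Among smooth muscle and renin cell markers 8 of 9 were detected: the myosin light chain Myl9 with 1471 ± 44.4 FPKM, the smooth muscle actin Acta2 with 72.8 ± 1.88 FPKM, Tagln with 61.2 ± 3.14 FPKM and Akr1b7 with 24.8 ± 1.12 FPKM. Calponin (Cnn1) was listed at 0. Of 8 fibroblast markers 3 were detected, Pdgfra (48.1 ± 1.35 FPKM), Col1a2 (16.035 ± 0.285 FPKM) and Pi16 (4.39 ± 0.606 FPKM), and Col1a1, Col3a1, Dcn and Lum were listed at 0. The smooth muscle and renin list lay -2.37 from the pooled markers (permutation test across genes, Benjamini-Hochberg adjusted p = 0.038) and the fibroblast list -5.24 (adjusted p = 0.0001). The smooth muscle call ended with a pseudocount of 0.1 FPKM (-2.59, adjusted p = 0.058) and against endothelial markers alone (-1.41, adjusted p = 0.28), and the adjusted permutation p ranged from 0.0095 to 0.28 over all alternatives.

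Some members of the arterial and of the venous and peritubular endothelial lists were detected, and the lymphatic ones were not. Mesangial and endothelial cells were mixed, so which of them made these transcripts cannot be told. The arterial list had 6 of 8 members detected, led by the ephrin Efnb2 (634 ± 9.26 FPKM), the gap junction genes Gja5 (95.2 to 104 FPKM over the aliquots) and Gja4 (32.6 ± 0.653 FPKM) and the Notch ligand Dll4 (13.7 ± 1.16 FPKM), with Bmx and Fbln5 at 0.0118 and 0.117 FPKM. The venous, lymphatic and peritubular list had 3 of 8: Nr2f2 with 459 ± 26.2 FPKM, the diaphragm gene Plvap with 93.7 ± 4.43 FPKM and Ephb4 with 17.3 ± 0.290 FPKM, and the lymphatic genes Prox1, Lyve1 and Pdpn were listed at 0. Their differences from the pooled markers were -2.98 (permutation test across genes, Benjamini-Hochberg adjusted p = 0.015) and -4.25 (adjusted p = 0.0012). The arterial call ended against endothelial markers alone (-2.02, adjusted permutation p = 0.16; range over all alternatives 0.0045 to 0.16), and the 2 subtype lists were not tested against each other.

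As a description of these libraries, each list's median was placed among 10000 random lists of the same size drawn from the 11142 genes above 0. The mesangial and endothelial lists lay at percentile 100, above every random list, and the 7 selection genes at 99.7. The podocyte list lay at 2.57, smooth muscle and renin cells at 68.9, arterial endothelium at 51.3 and venous, lymphatic and peritubular endothelium at 0.080. The parietal, tubule, distal, fibroblast, macrophage, lymphocyte, neutrophil and erythroid lists were at 0. Most positions depend on the background chosen. The podocyte list lay at 99.4 among random lists from all 39304 rows, most of them at 0, and at 0 among genes with a mean of at least 1 FPKM. Of 33 lists, gene groups included, 6 stayed at or above 99 with each of these backgrounds and 9 stayed at 0. The percentile counts random lists with a lower median, so those 9, each with a median of 0 FPKM, could only lie at 0. The other 18 spanned 13.0 to 100 percentile points, so their positions here and in the gene groups that follow hold for genes above 0 alone.

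Matrix genes were examined in 3 groups. Of 9 basement membrane collagen genes 7 were detected, with Col4a2 at 109 ± 1.18 FPKM, Col4a1 at 103 ± 1.53 FPKM, Col4a3 at 77.7 ± 2.82 FPKM and Col8a1 at 22.1 ± 0.928 FPKM, and with Col4a5 and Col4a6 at 0.786 ± 0.0876 and 0.397 ± 0.0803 FPKM. Of 15 laminins and other basement membrane glycoproteins 9 were detected, led by nidogen (Nid1, 86.2 ± 0.356 FPKM), Lamb1 (83.1 ± 2.41 FPKM), Lamc1 (45.2 ± 4.01 FPKM) and Lama4 (13.6 ± 0.621 FPKM), while Lama1, Lamb3 and Lamc3 were listed at 0. Interstitial matrix genes had 7 of 17 members detected and 9 listed at 0 in each aliquot. The proteoglycan Bgn had 614 ± 21.9 FPKM and the collagen-binding Sparc 459 ± 1.21 FPKM, followed by Col1a2 and Col6a3 (15.2 ± 0.906 FPKM), whereas Fn1, Col1a1, Col3a1 and Vcan were listed at 0. The medians of these groups lay at percentiles 45.3, 29.6 and 0 among random lists, the last fixed by a median of 0 FPKM.

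Contractile and cytoskeletal genes were detected for 14 of 15 members, at percentile 100. Beside Myl9 the highest were caldesmon (Cald1, 1425 ± 16.8 FPKM), vimentin (Vim, 447 ± 16.9 FPKM) and the non-muscle myosin Myh9 (379 ± 51.1 FPKM). Among integrins 9 of 14 were detected, at percentile 92.6: Itga8 and its partner Itgb1 (551 ± 3.57 FPKM) stood above Itga4 (49.3 ± 2.52 FPKM) and Itga9 (39.5 ± 1.93 FPKM), and Itga5 and Itgb4 were listed at 0. Insulin-like growth factor binding proteins split evenly: Igfbp5, Igfbp7 (572 ± 4.70 FPKM) and Igfbp4 (214 ± 0.367 FPKM) were detected, and Igfbp2, Igfbp3 and Igfbp6 were listed at 0, with the list at percentile 61.3.

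Of 23 vasoactive ligands, enzymes and receptors 12 were detected, at percentile 0.260. The angiotensin receptor Agtr1a had 481 ± 2.50 FPKM, the endothelin-converting enzyme Ece1 414 ± 7.27 FPKM, the endothelin receptor Ednrb 139 ± 2.84 FPKM and the natriuretic peptide clearance receptor Npr3 49.6 ± 1.19 FPKM. The angiotensin receptor genes Agtr1b and Agtr2, Ace and Ptgs2 were listed at 0. Growth factors and their receptors were detected for 23 of 31 members, at percentile 96.9, led by the VEGF co-receptor Nrp1 (746 ± 3.63 FPKM), Ccn2 (318 ± 10.2 FPKM), Eng and the TGF-beta co-receptor Tgfbr3 (268 ± 0.855 FPKM). Vegfb, Angpt1 and Igf1 were listed at 0 and Egfr had 0.108 ± 0.0668 FPKM. In the Notch pathway 9 of 12 genes were detected, at percentile 53.6: the ligand Jag1 had 83.9 ± 0.853 FPKM, and the target genes Heyl and Hes1 had 45.6 ± 3.36 and 37.3 ± 3.04 FPKM, while Jag2 and Hey1 were listed at 0.

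Of 29 lineage transcription factors 18 were detected, at percentile 35.6. After Gata3 came Ets1 (501 ± 3.44 FPKM), Nr2f2 and Fli1 (221 ± 16.2 FPKM), and Gata6, Sox7, Foxd1 and Pax2 were listed at 0. Immediate early and stress genes, which rise within minutes of tissue handling, were detected for 7 of 14 members, at percentile 0.80. The phosphatase gene Dusp1 had 148 ± 5.04 FPKM, Zfp36 15.6 ± 0.536 FPKM, Jun 13.2 ± 1.27 FPKM and Ier3 3.71 ± 0.672 FPKM, and Fos, Junb and Atf3 were listed at 0. Cell cycle genes were detected for 2 of 10 members, Pcna (44.8 ± 4.09 FPKM) and Cdk1 (20.6 ± 1.01 FPKM), at percentile 0, and Top2a, Ccnb1, Aurkb and Rrm2 were listed at 0.

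Genes of complement regulation and antigen presentation were detected for 6 of 11 members, at percentile 52.7. The class I genes B2m (2249 ± 66.1 FPKM), H2-D1 (598 ± 4.05 FPKM) and H2-K1 (114 ± 4.03 FPKM) led, and C3, Cfb and the class II gene H2-Aa were listed at 0. Coagulation and fibrinolysis genes were detected for 7 of 11 members, at percentile 44.6, with Plat, the clotting factor gene F8 (144 ± 2.92 FPKM), the inhibitor Tfpi (61.4 ± 1.31 FPKM) and thrombomodulin (Thbd, 32.9 ± 0.590 FPKM) highest, and with Procr, Tfpi2 and F3 listed at 0.

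Genes whose mutation causes inherited podocyte disease were detected for 21 of 29 members, at percentile 8.46. The highest were genes of wide expression, Actn4 (317 ± 7.37 FPKM), Arhgdia (69.7 ± 1.24 FPKM) and Myo1e (53.1 ± 0.570 FPKM), together with Wt1, and Anln, Coq2, Coq8b and Cubn were listed at 0. All 8 widely expressed reference genes were detected, at percentile 100, from Actb, Ywhaz, Eef1a1 (1247 ± 46.6 FPKM) and Ppia (1111 ± 28.9 FPKM) downwards. Of 13 mitochondrially encoded genes 12 were detected, at percentile 100. Of 5 sex-linked genes the Y-linked Uty (68.8 ± 0.601 FPKM), Ddx3y (59.5 ± 1.73 FPKM), Eif2s3y (47.4 ± 0.419 FPKM) and Kdm5d (1.85 ± 0.162 FPKM) were detected, and Xist was listed at 0 in each aliquot, matching the male sex in the labels. That list lay at percentile 93.3.

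Pairs of related genes, fixed before the data were examined, were compared within each aliquot as the log2 ratio of (FPKM + 1). In 20 of 25 pairs the first gene was higher in 3 of 3 aliquots and in 5 pairs the second gene was. The 3 values per pair cannot give a two-sided exact p below 0.25, so none is printed. Among collagen IV chains Col4a2 exceeded Col4a4 (2.42 ± 0.0846 FPKM) by 5.01 ± 0.04, whereas Col4a1 exceeded Col4a3 by 0.40 ± 0.06. Lamb1 exceeded Lamb2 (9.55 ± 0.721 FPKM), the beta chain of the mature glomerular basement membrane, by 3.00 ± 0.08, and Lama4 exceeded Lama5 (10.3 ± 0.349 FPKM) by 0.37 ± 0.11. The mesangial integrin Itga8 exceeded Itga3 (18.5 ± 1.01 FPKM) by 5.10 ± 0.08, and Vim exceeded Des (114 ± 2.22 FPKM) by 1.97 ± 0.07. Igfbp5 exceeded Igfbp7 by 0.73 ± 0.03 and Acta2 exceeded Tagln by 0.25 ± 0.05. Gata5 had 0, 0 and 0.0278 FPKM beside Gata3, and Agtr2 was listed at 0 beside Agtr1a, as was Angpt1 beside Angpt2 (107 ± 0.397 FPKM). Nos3 had 1 read in all beside Edn1 (1.28 ± 0.284 FPKM), so no fold is given for these 4 pairs.

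In the vascular pairs, the VEGF receptor Kdr (143 ± 4.77 FPKM) exceeded Flt1 (48.2 ± 0.146 FPKM) by 1.55 ± 0.05, and Flt1 exceeded the lymphatic receptor Flt4 (0.147 ± 0.00967 FPKM) by 5.42 ± 0.01. Tek exceeded Tie1 (14.4 ± 0.924 FPKM) by 1.49 ± 0.09, Ehd3 exceeded Plvap by 1.73 ± 0.05, and Emcn exceeded Vwf (0.162 ± 0.0515 FPKM) by 10.11 ± 0.04. The flow-regulated Klf2 (32.8 ± 1.30 FPKM) exceeded Klf4 (14.6 ± 1.53 FPKM) by 1.12 ± 0.12. Pdgfrb (70.2 ± 1.12 FPKM) exceeded Pdgfra by 0.54 ± 0.06. The second gene was higher for Ednra (13.9 ± 0.478 FPKM) against Ednrb (-3.23 ± 0.07), Pdgfb (36.5 ± 1.07 FPKM) against Pdgfa (161 ± 8.28 FPKM; -2.11 ± 0.10) and Tgfb1 (0.208 ± 0.0727 FPKM) against Tgfb2 (3.43 ± 0.122 FPKM; -1.88 ± 0.12). The same held for Vegfc (9.68 ± 0.397 FPKM) against Vegfa (16.3 ± 1.73 FPKM; -0.69 ± 0.11) and Notch3 (10.2 ± 0.541 FPKM) against Notch1 (18.0 ± 0.784 FPKM; -0.76 ± 0.06). For Flt4, Vwf and Tgfb1 the added 1 FPKM exceeds the gene's own level, which reduces the size of the log2 ratio and its SD. Without it the ratios of mean FPKM were 328 for Flt1/Flt4, 7927 for Emcn/Vwf and 0.0608 for Tgfb1/Tgfb2. These rest on at most 8 reads per aliquot of the lower gene. Some directions depend on gene length, in alternatives chosen after seeing the data. Scaled from the mean to the longest transcript length, the Notch pair turned to 0.36. Scaled from the implied length, which can miss a whole factor, it turned to 1.54, Col4a1/Col4a3 to -0.86 and Vegfc/Vegfa to 0.10. Sizes changed as well with scaling from the mean: Pdgfrb/Pdgfra became 1.81, Klf2/Klf4 2.06 and Flt1/Flt4 4.29, while Ehd3/Plvap became 1.71.

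**Figure D2:**
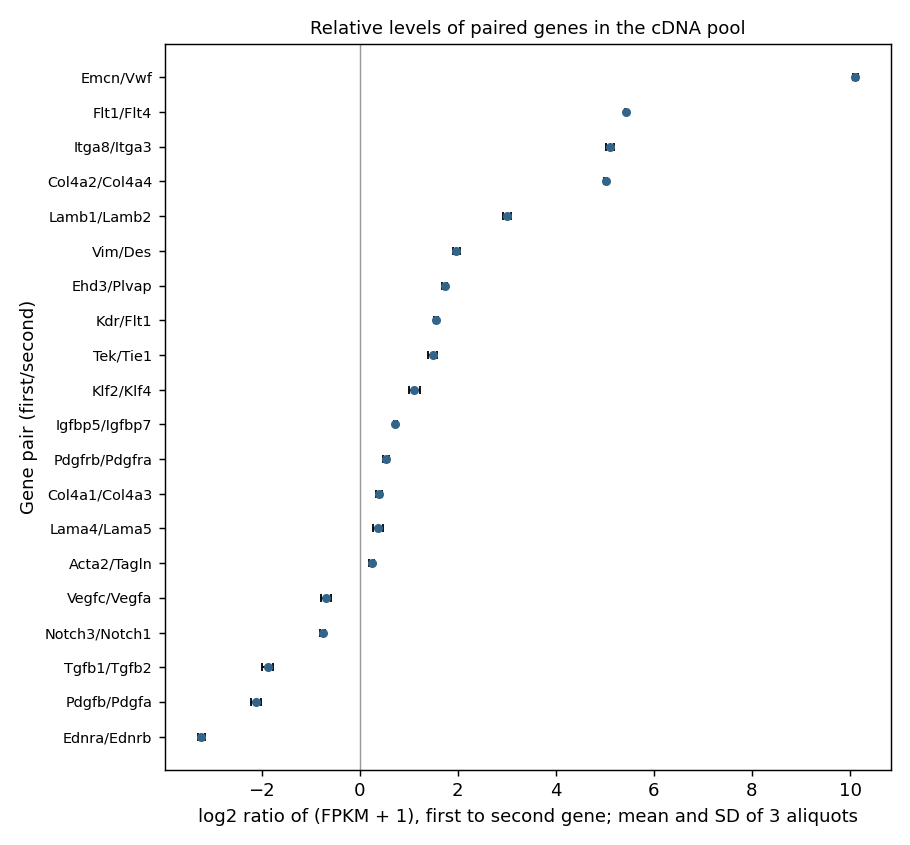
Log2 ratios of paired genes. Each point is the mean over 3 aliquots of the log2 ratio of (FPKM + 1) of the first to the second gene (x axis), with the SD as a bar, for 20 of the pairs, sorted by ratio; the 4 pairs with a gene of at most 3 reads are among those not drawn. Ratios run from -3.23 for Ednra/Ednrb to 10.11 for Emcn/Vwf, and every SD is at most 0.12. For Flt4, Vwf and Tgfb1, all under 1 FPKM, the added 1 FPKM reduces the size of the ratio and its SD.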

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

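All tests in this part were chosen after the results were seen. Rows without an Ensembl gene identifier entered no list and no gene pair and carried signal: 123 of 125 reached 1 FPKM in every aliquot, the highest had 169 ± 1.07 FPKM (SD, n = 3), and together they took 0.324% of reads.

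Podocyte transcripts were present in a pool from which podocytes were left out: Wt1 had 101 ± 3.18, Nphs1 37.6 ± 2.37 and Synpo 36.7 ± 1.04 FPKM (SD, n = 3). Reads of an overlapping gene of GENCODE M21 are argued against by a median of 0% of exonic bases shared with another such gene over the 11 detected podocyte genes (largest 30.7%). Overlap with rows that have no coordinates here could not be tested. Free RNA of all cell types in the digest stays open: of 69 markers of nephron epithelia, blood cells and fibroblasts 4 reached 1 FPKM in every aliquot (Fcer1g, Pdgfra, Col1a2 and Pi16), and 62 were listed at 0, which excludes nothing here. RNA of podocytes in the pool, from a well holding more than 1 cell or free RNA of podocytes alone, may be a source and cannot be told apart from low expression by the pooled cells. It would bring most podocyte markers, and 8 of 15 were detected (12 at 0.5 FPKM), with no pure podocyte library here to set the level; no biological explanation was tested.

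Many list members were listed at 0: across the mesangial, endothelial, interstitial matrix, contractile, vasoactive, growth factor, IGF-binding protein, immediate early and coagulation lists, 31 of 138 had 0 FPKM in each aliquot. Among them were Cldn5, Fn1, Fos and Junb, and also Col1a1, Col3a1 and Dcn, markers of fibroblasts, and genes the pooled cells need not express. Reads lost to an overlapping gene of GENCODE M21 are argued against, as 0% of the 31 shared over 50% of their exonic bases with another such gene. Overlap in the authors' own annotation, or with rows that have no coordinates here, could not be tested. Too few reads stay open, as 2 (6.06%) of 33 members at 0 in aliquot 1 had a read in another aliquot but the other 31 are the pattern itself. Extreme GC content is not decided by these values. Of the 31, 71.0% lay within the central 90% of the GC content of detected members, 43.4% to 59.0%. The median GC content was 53.9% for the members at 0 and 52.3% for detected members. Loss of transcripts in the 30 cells before pooling, steps of the authors' counting and true absence were not tested.

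Gata3 stood at rank 12 of all genes. With gene lengths changed to the longest annotated transcript it had 852 ± 59.2 FPKM and rank 32, whether scaled from the mean or from the implied length. The short length of 915 bases is therefore a candidate explanation for part of its rank, while its 83276 reads over the 3 aliquots are unaffected by it. These settings moved the median detected gene by -0.86 and -0.72 on the log2 scale, so part of the fall in its FPKM is shared with other genes. No biological explanation was tested.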

How the results depend on the processing

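The gene length and Podxl settings were chosen after seeing the data. Of 150 alternatives of the list comparisons, 144 kept their direction and their side of the threshold, 6 lost the call and 0 reversed. Many of them concern nephron epithelial and blood cell lists, with 57 of 61 members at 0, whose differences could hardly reverse. Runs without an aliquot use the same cDNA pool, so they vary library construction and sequencing only. Mesangial minus podocyte markers ranged from 5.33 to 6.67 and endothelial minus podocyte markers from 3.06 to 5.16. Calls were lost for endothelial minus mesangial markers with medians (-1.52) and with members of at least 0.1 FPKM (-1.23). They were also lost for smooth muscle and renin cells with a pseudocount of 0.1 FPKM (-2.59) and against endothelial markers alone (-1.41), for arterial endothelium against endothelial markers alone (-2.02), and for macrophages with members of at least 0.1 FPKM (-1.13), where 1 gene was left. Against endothelial markers alone the reference mean was 5.79 in place of 6.75, which by itself makes those differences smaller. The limit of 0.1 FPKM took Cldn5 and Nos3 out of the endothelial list, which raises its mean. What ended the remaining calls was not tested. With members of at least 0.1 FPKM, the parietal, proximal, distal, lymphocyte, neutrophil and erythroid lists had no member left and gave no value. Genes detected ranged from 6701 at 5 FPKM to 9026 at 0.5 FPKM. Detected podocyte markers fell from 8 to 4 and immediate early genes from 7 to 3 at 5 FPKM, while 12 podocyte markers were detected with FPKM rescaled to a sum of 1000000; 295 other counts per list stayed within 1.5 times. The lowest r was 0.9895 with a pseudocount of 0.1 FPKM, 0.9959 over genes of at least 1 FPKM and 0.9967 to 0.9972 with an aliquot left out. The median coefficient of variation of genes of at least 10 FPKM, 3.50% with all aliquots, was 2.55% to 3.03% with an aliquot left out, since an SD of 2 values has a lower median, and 3.15% and 3.16% with lengths scaled from the mean and from the implied to the longest transcript. Notch3/Notch1 turned to 0.36 and 1.54 by these, and with the implied length Col4a1/Col4a3 turned to -0.86 and Vegfc/Vegfa to 0.10. Only the length factors differ in these runs. For Notch3 the implied length of 8044 bases was near the longest of 8016, so scaling from the implied length hardly moved its FPKM. Which length is right was not tested. Another 49 ratio alternatives moved by over 1 SD without a change of sign and 97 did not. Of 198 random-list positions 95 moved beyond their interval, by up to 100 percentile points with another background, 30.4 with list means and 6.65 without an aliquot. Podocyte markers went from 2.57 to 99.4 with all rows and to 0 with genes of at least 1 FPKM. The other backgrounds left 15 of 33 lists at 0 or at least 99. The 9 at 0 have a median of 0 FPKM and could take no other position. The ranks of Malat1, Actb, Gata3 and Serpine2 moved with both changes of gene length and did not move with any aliquot left out. Depth limits values under 1 FPKM, and the median coefficient of variation was 35.1% for genes of 0.1 to 1 FPKM.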

Other observations

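The gene groups in this part were chosen after the data were seen, and so were the genes named from them. All 11 genes of caveolae and related membrane coats reached 1 FPKM in every aliquot, with Ehd3 at 313 ± 4.42 FPKM, Cav2 at 233 ± 8.31 FPKM, Cav1 at 204 ± 5.71 FPKM and Ehd4 at 190 ± 3.24 FPKM (SD, n = 3 throughout). The adrenomedullin system was present on both sides: the receptor Calcrl had 589 ± 28.8 FPKM, its partner Ramp2 197 ± 10.4 FPKM and the ligand Adm 112 ± 2.79 FPKM, while Ramp1 and Adm2 were listed at 0 in each aliquot and Ramp3 had 7.53 ± 0.424 FPKM.

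Among 13 metalloproteases and inhibitors 5 were detected, namely Adamts5 (255 ± 3.65 FPKM), Timp3 (207 ± 3.56 FPKM), Adamts1 (178 ± 3.94 FPKM), Timp2 (155 ± 0.557 FPKM) and Mmp2 (39.1 ± 2.10 FPKM), and Timp1, Mmp3 and Mmp9 were listed at 0. Of 15 genes of the bone morphogenetic protein pathway 6 were detected, led by the secreted antagonist Fstl1 with 1591 ± 39.4 FPKM and the receptor Bmpr2 with 66.8 ± 1.60 FPKM, and the antagonists Grem1, Nog and Chrd were listed at 0. Of 18 semaphorins, plexins and neuropilins 12 were detected, with Nrp1 at 746 ± 3.63 FPKM and Sema5a at 66.6 ± 2.53 FPKM. Of 9 receptors and enzymes of lysophospholipid signalling 4 were detected: S1pr3 (103 ± 2.16 FPKM), Lpar4 (22.9 ± 0.524 FPKM), S1pr1 (16.6 ± 0.281 FPKM) and Lpar6 (9.28 ± 0.566 FPKM).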
